A study of Xenopus laevis with 4 samples.

How the data were processed

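The series holds 4 spotted two-colour arrays in 2 sets of 2 arrays each, and each set carries other probes. On every array, RNA of Xenopus laevis animal caps from embryos injected with mRNA of a dominant negative BMP receptor (DNBR) was set against RNA of uninjected control caps. Per the labels, DNBR RNA was labelled with Cy5 and control RNA with Cy3, 50 µg of total RNA went into labelling, hybridisation ran for 20 hours at 65 °C, and the slides were read with a GenePix scanner. The labels name GenePix Pro, Cyber-T (a regularised t-statistic) and GeneData Expressionist for the analysis by the authors. The normalisation within arrays, any filter on dim or bad spots and the averaging of spots are not given in the sources used here.

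The deposited values are natural log ratios of the 2 channels, with no signal of either channel, no flag and no error beside them. The log base was worked out from the values. The exponential of every value at or above 0 was a whole number of hundredths on all 4 arrays, within 0.002 of a hundredth. Below 0, the exponential was a whole number of hundred-thousandths for at least 99.9% of values, within 0.005 of that step. Bases 2 and 10 gave whole hundredths for at most 0.186% of values above 0. The direction of the ratio is not stated in the deposited tables. It was taken as Cy5 over Cy3, DNBR over control, as the order of the channels in the labels has it, and is called likely. Higher and lower below carry that assumption, and every sign would turn if it were wrong.

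The log ratios were converted to log2. The medians as deposited were 0.014 and -0.19 for the arrays of set 1, and -0.091 and -0.075 for those of set 2, on the log2 scale, and each array was centred on its median. Set 1 held 11918 probes, of which 111 are named as controls in their IDs and were left out of the tests and of the centring, leaving 11807. Set 2 held 18116 probes with no such name. No value was missing and no ID was repeated. No column held values of a sample outside the series (0 columns). No floor or ceiling was seen, since the lowest and highest value of each array occurred once.

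Each set was tested alone with limma 3.58.1 in R 4.3.3, with the mean log2 ratio of the 2 arrays against 0 (lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment within the set at 0.05. Beside the test, probes were counted that were at least 2-fold from 1 in the same direction on both arrays, a fixed rule of size. Values of single tested probes are mean ± SD over 2 arrays, and any other SD is given with its unit. The labels do not say whether the arrays of a set came from separate batches of embryos, so the p-values measure the spread between 2 hybridisations, which may be technical. The dyes were not swapped according to the labels, so a dye effect that repeats on both arrays stays in every ratio. With no channel signals, the precision is limited by the number of arrays, and no filter on dim probes and no intensity-dependent normalisation could be run.

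The test was tried on simulated data, 20 sets of values per array set with 200 changed probes each, drawn with the fitted spread of that set. In set 1 (11807 probes) it recovered 24.0% of changes of 1.5-fold and 91.2% of changes of 2-fold. In set 2 (18116 probes) it recovered 89.5% of changes of 1.5-fold and all changes of 2-fold (100%). Among simulated calls the median false share was 14.1% in set 1, between 2.94% and 18.2%, and 10.5% in set 2, between 2.70% and 28.3%. With 1 residual degree of freedom per probe, the limma calls were thus somewhat too many for a nominal 5% error in these simulations. The noise in these simulations was independent between arrays and held no trend over plates or well positions. Separate simulations with no changed probe added each array's medians by well position to such noise. A median of 7 probes in set 1 and 1 in set 2 were then called. The false share among the real calls may differ and was not measured.

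The probe IDs (such as XL007b09) name no gene. They were read as a plate and a well of a 384-well plate. Of 30034 IDs, 0 matched a symbol, synonym, locus tag or accession of the NCBI gene table for the X. laevis v10.1 assembly, so no probe is named by gene and no genomic position is given. Gene lists for neural, epidermal and mesendodermal markers and for BMP targets, and the check of the injected receptor, had been fixed before the data were examined and were not run. The rule fixed then for unnamed probes was followed: per set, the 2 highest and the 2 lowest probes by mean log2 ratio among those past the threshold with the same sign on both arrays.

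The alternatives fixed before the data were examined were values as deposited, scaling or quantile normalisation between arrays, a robust eBayes fit, a regularised t after Cyber-T, adjustment over both sets, other thresholds and leaving out each array. Centring within well positions or plates, leaving out plates, keeping the control-named probes and testing against a change of at most 1.2-fold were added after seeing the data. Well positions are 32 groups made of 8 row classes (rows 8 apart share a class) and 4 column classes (columns 4 apart share a class), the pattern that the medians showed.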

Results

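Gene expression was compared between Xenopus animal caps turned towards a neural fate by blocking BMP signalling and untreated caps, to find neural genes. The animal cap is the upper, ectodermal part of the blastula, which forms epidermis in isolation, and neural tissue when BMP signalling is blocked. Embryos received 4 ng of mRNA for a dominant negative type I BMP receptor (DNBR), caps were cut at stages 8 to 8.5, and RNA was taken at stage 10.5, the early gastrula. Both RNAs were hybridised together on each of 4 spotted arrays, 2 arrays of set 1 (11807 tested clones from 55 plates) and 2 of set 2 (18116 clones from 56 plates). Values are log2 ratios of DNBR over control caps, median-centred per array, and this direction is likely rather than stated in the deposited tables.

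In set 1, 362 of 11807 clones (3.07%) differed between DNBR and control caps at an adjusted p under 0.05 (limma), 154 higher and 208 lower in DNBR caps. The smallest change called was 1.60-fold, and the median called change was 1.81-fold. The clones XL007b09 and XL052i14 rose most, by 2.42 ± 0.096 and 2.21 ± 0.26 on the log2 scale (SD, n = 2), which is 5.37-fold and 4.64-fold. The clones XL005k21 and XL022i15 fell most, with log2 ratios of -2.65 ± 0.069 and -2.51 ± 0.64 (SD, n = 2), or 6.26-fold and 5.71-fold lower. The limma adjusted p of these 4 clones lay between 4.56e-08 and 2.998e-07. Of the clones in set 1, 79 were at least 2-fold from 1 in the same direction on both arrays, 33 higher and 46 lower, and all 79 were also past the limma threshold. Only 1 clone was 2-fold in opposite directions on the 2 arrays, and 1.56 clones would be 2-fold alike on both arrays if the arrays were independent. At least 4-fold on both arrays were 2 higher and 5 lower clones, and none (0) reached 8-fold. The share of lower clones among the 79 was 58.2% (95% exact binomial interval 46.6% to 69.2%, exact binomial p = 0.177 against equal shares). At 1.5-fold on both arrays 105 clones were higher and 167 lower, 61.4% lower (95% exact binomial interval 55.3% to 67.2%, exact binomial p = 2.05e-04), and at 3-fold 11 were higher and 10 lower. Both binomial p-values count each clone as independent, although clones in the same well rows shared shifts. With values as deposited the 2-fold split was 29 higher and 59 lower. The arrays taken alone differed in direction at 2-fold, with more lower clones on array 1 and more higher clones on array 2.

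With values as deposited, 306 clones passed, 75 higher and 231 lower, in place of 154 and 208. Adjusted over both sets, 1040 passed, and the split turned to 547 higher and 493 lower. With plates centred 557 passed, 275 higher and 282 lower. The regularised t after Cyber-T called 87, 36 higher and 51 lower. After centring within well positions 264 passed, of which 205 were among the 362, all 205 with the same sign, while the 2-fold count was 74. Across all clones the arrays of set 1 correlated with Pearson r = 0.47 and Spearman rho = 0.42 (across clones, which are not independent replicates).

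In set 2, 7199 of 18116 clones (39.7%) passed the same limma threshold, 3343 higher and 3856 lower in DNBR caps. The direction of the split differed between plates. Plates 56 to 65, a group chosen after its values were seen, gave 237 higher and 1541 lower calls (58.5% of their clones). The other 45 numbered plates gave 3077 higher and 2260 lower calls (35.7%). These splits depend on the centring, which used a common median for all plates of the set. With plates 56 to 65 left out and the rest, plate XL0c2 included, centred again, 6583 clones passed. Of these, 3174 were higher and 3409 lower, so the excess of higher calls did not remain. With values as deposited the split was 1364 higher and 3512 lower. Most of these changes were small: the smallest was 1.17-fold and the median 1.33-fold, and 2007 clones (679 higher, 1328 lower) passed a limma test against a change of at most 1.2-fold. The clones XL0c2h11 and XL0c2h08 rose most, by 7.48 ± 0.48 and 7.32 ± 0.078 on the log2 scale (SD, n = 2), which is 178-fold and 160-fold. The clones XL097k08 and XL110l06 fell most, with log2 ratios of -3.94 ± 0.023 and -3.75 ± 0.18 (SD, n = 2), or 15.4-fold and 13.4-fold lower. The limma adjusted p of these 4 clones lay between 2.218e-08 and 7.714e-07. At least 2-fold alike on both arrays were 355 clones, 76 higher and 279 lower, and all 355 passed the limma threshold. No clone (0) was 2-fold in opposite directions, and 9.90 would be 2-fold alike on both arrays if the arrays were independent. At least 8-fold on both arrays were 13 higher and 7 lower clones.

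**Figure D1:**
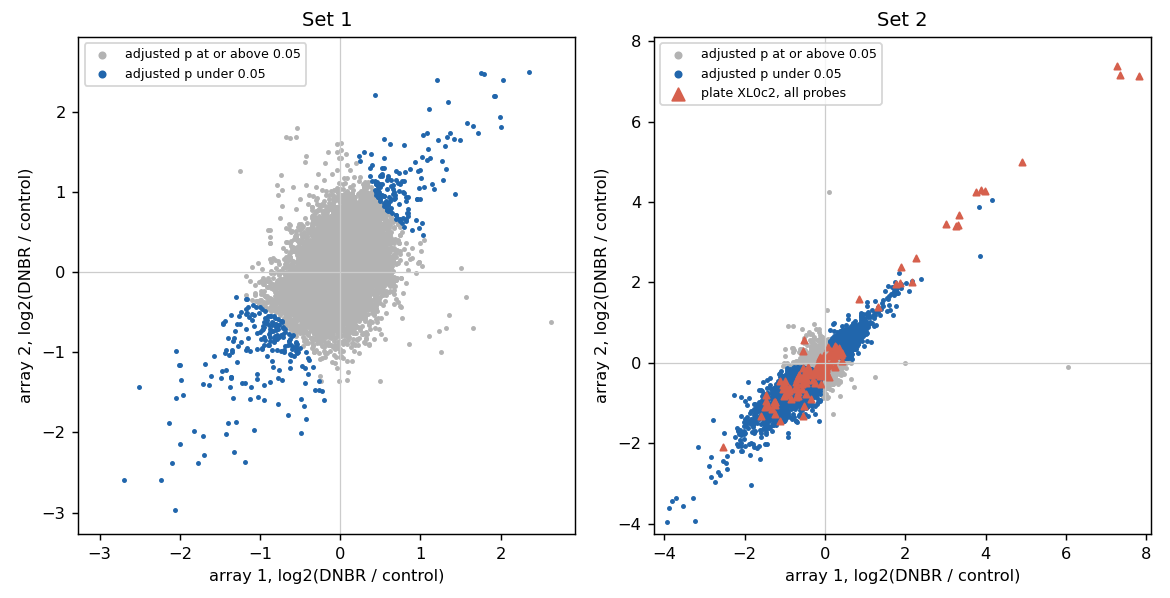
Log2 ratio of DNBR over control caps on array 2 against array 1, one point per clone, for set 1 (left) and set 2 (right). Clones past the limma threshold are blue and all clones of plate XL0c2 are red triangles. The arrays of set 2 lie closer to one line (r = 0.87) than those of set 1 (r = 0.47), and the 3 clones near a log2 ratio of 7 are on plate XL0c2.

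The arrays of set 2 agreed more closely than those of set 1, with Pearson r = 0.87 and Spearman rho = 0.81 across clones. The pooled SD between the 2 arrays of a set was 0.154 on the log2 scale in set 2 and 0.287 in set 1. With the prior variance of set 1 used for every clone, 9.18% of set 2 clones passed in place of 39.7%, and with that of set 2, 42.1% of set 1 clones passed in place of 3.07%. These swaps also took the degrees of freedom of the other set and left out each clone's own variance. The part due to the spread alone is thus not isolated. When the sign of one array was turned, limma called 1 clone in set 1 (55 at an unadjusted p under 0.05) and none (0) in set 2 (4 at an unadjusted p under 0.05), and the regularised t after Cyber-T called none (0) in either set. These counts are low in part by construction, since changes shared by both arrays then enter the spread.

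Lower clones outnumbered higher clones in set 2 at 2-fold, at 78.6% of the 355 (95% exact binomial interval 74.0% to 82.7%, exact binomial p = 2.24e-28). The intervals, binomial and Fisher p-values for these shares count each clone as independent. However, several clones can come from 1 gene, clones of a plate or row share shifts, and equal shares depend on the centring. These p-values thus do not measure how far a split would repeat in other caps. Among stronger changes the excess was not shown over the whole set. At 3-fold 42 were higher and 60 lower (58.8% lower, exact binomial p = 0.0918). At 4-fold 18 were higher and 27 lower (60.0% lower, exact binomial p = 0.233). Plate XL0c2 held 13 of these 18 higher clones and 1 of the 27 lower ones. At 4-fold, plates 56 to 65 held 2 higher and 11 lower clones, and the other 45 numbered plates 3 higher and 15 lower. On the numbered plates lower clones thus outnumbered higher ones at 4-fold too. The 2-fold share was higher than in set 1 (Fisher's exact test, two-sided p = 3.01e-04), but after centring within plates 79 clones of set 2 were higher and 163 lower (67.4% lower, interval 61.1% to 73.2%), and the difference from set 1 was not past 0.05 (Fisher's exact test against set 1 without plate centring, p = 0.174). The excess came in part from 10 plates. On plates 56 to 65, a group chosen after its values were seen, 177 of 3039 clones (5.82%) were at least 2-fold lower on both arrays, against 94 of 14945 (0.629%) on the other 45 numbered plates of the set. On plate 59 alone, 55 of 270 clones were lower to this degree. Higher clones on plates 56 to 65 were 15 (0.494%), against 44 (0.294%) on the other numbered plates. Without plates 56 to 65, 58 clones were higher and 113 lower (66.1% lower, interval 58.5% to 73.1%, exact binomial p = 3.14e-05). The difference from set 1 was then not past 0.05 (Fisher's exact test, p = 0.259). That follows in part from the choice, since leaving out plates chosen for low values lowers the share of lower clones. The 171 clones left also give the comparison less power.

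**Figure D2:**
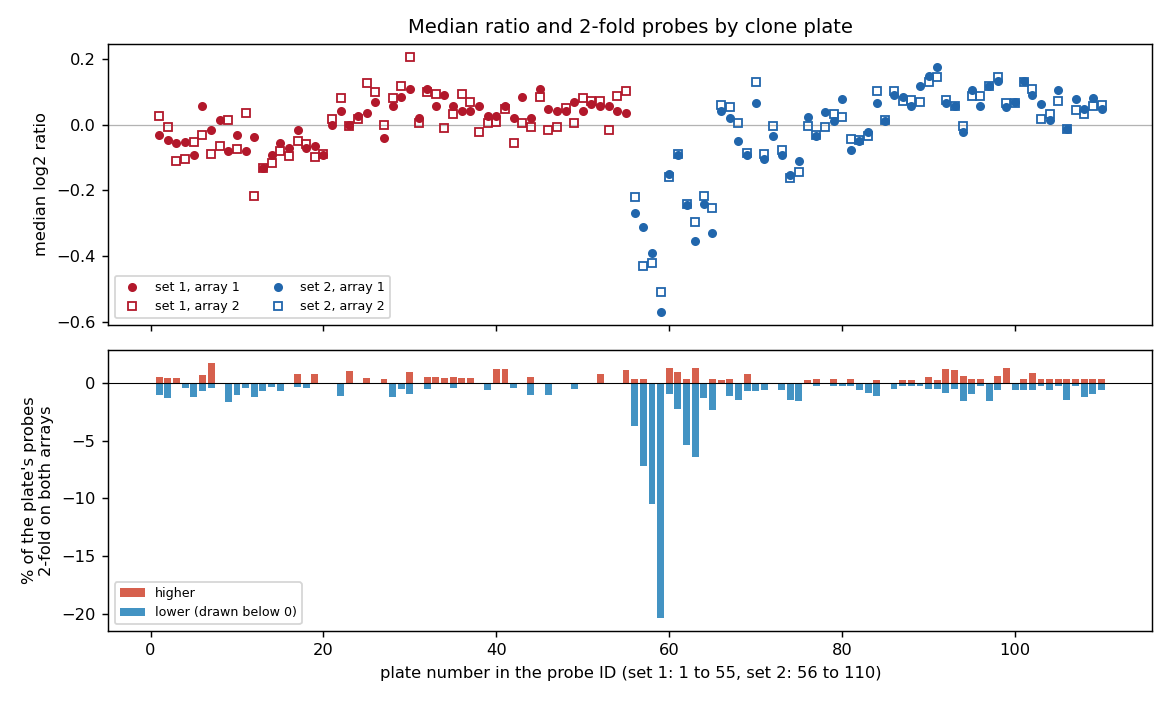
Top, median log2 ratio of each clone plate on array 1 (filled circles) and array 2 (open squares) of set 1 (red) and set 2 (blue). Bottom, percent of each plate's clones at least 2-fold higher (above 0) or lower (drawn below 0) on both arrays. Plate XL0c2 is not drawn. Most of plates 56 to 65 stand below the other numbered plates of set 2, with the most lower clones on plate 59. The ranges overlap: plate medians averaged over the arrays ran from -0.54 to -0.090 on plates 56 to 65. On the other numbered plates of set 2 they ran from -0.16 to 0.16.

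The medians of plates 56 to 65 averaged -0.29 ± 0.13 (SD, 10 plates) on the log2 scale, against 0.034 ± 0.073 (SD, 45 plates) for the other numbered plates. No p-value is given, since these plates were chosen for their low values. Both arrays showed it, with a median of -0.28 on array 1 and -0.27 on array 2.

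The strongest increases of the study were on 1 plate of set 2 whose ID departs from the numbered series, XL0c2, singled out after its values were seen. Of its 132 clones, 17 (12.9%) were at least 2-fold higher on both arrays, of the 76 such clones in the set, and 8 were at least 2-fold lower. It held 13 of the 18 clones at least 4-fold higher and 13 of the 20 highest clones of the set. Exactly 3 clones of set 2 were over 100-fold higher on both arrays, all on this plate, and the next highest clone of the set stood at 30.9-fold. Without the plate, 59 clones were 2-fold higher and 271 lower.

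Ratios also followed the position of a clone's well on its plate, and the trend over rows ran in the same direction on all 4 arrays. From rows a and i to rows h and p, the row median fell from 0.25 to -0.23 on array 1 and from 0.22 to -0.21 on array 2 of set 1. The same rows went from 0.12 to -0.076 on array 1 and from 0.21 to -0.11 on array 2 of set 2. The 32 position groups accounted for 36.3% and 17.8% of the variance of the ranked ratios on the arrays of set 1, and for 5.35% and 14.9% on those of set 2 (groups chosen from these medians, so with no p-value). The trend over columns did not repeat: in set 1 the last of the 4 column classes was lowest on array 1 (mean of its position medians -0.21) and highest on array 2 (0.028). The 2-fold counts after centring within positions were 74 in set 1 and 331 in set 2, and the limma count in set 2 was 6818, of which 5698 were among the 7199.

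**Figure D3:**
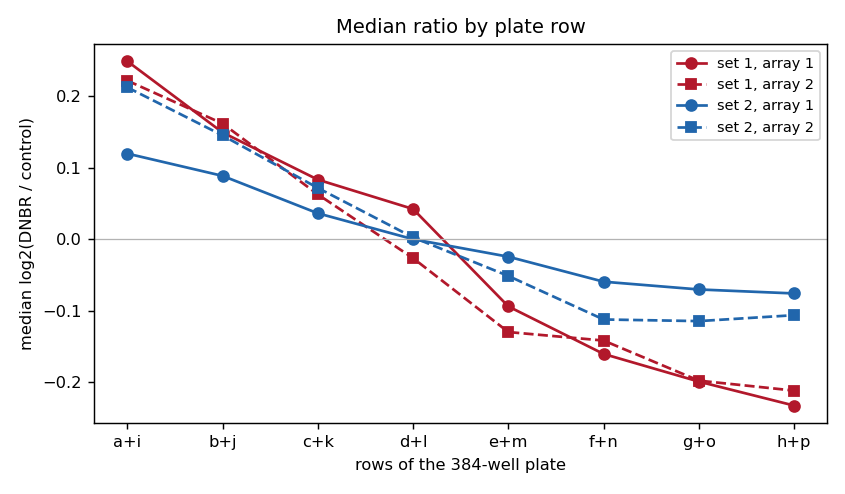
Median log2 ratio of clones by well row, with rows 8 apart pooled, for the 2 arrays of set 1 (red) and of set 2 (blue). The medians fall from rows a and i towards rows h and p on all 4 arrays, from 0.25 to -0.23 on array 1 of set 1.

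The 111 control-named probes of set 1, which were not tested, did not repeat between the arrays. Those in columns 3, 7, 11 and so on (55 probes) had a median log2 ratio of 0.52 (SD 0.28) on array 1 and -0.37 (SD 0.19) on array 2, and 52 of them had opposite signs on the 2 arrays. Those in columns 2, 6, 10 and so on (55 probes) had medians of -0.26 (SD 0.22) and 0.46 (SD 0.12), with opposite signs for 47.

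**Figure D4:**
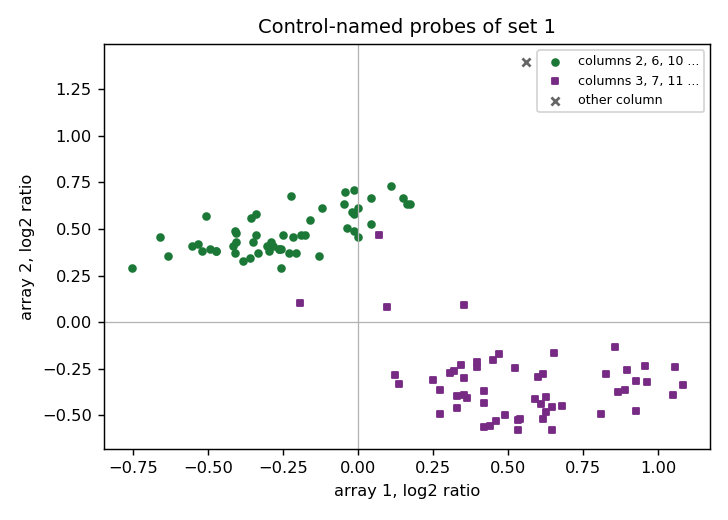
Log2 ratio on array 2 against array 1 of set 1 for the 111 control-named probes, by column class of the ID. The 55 probes of columns 2, 6, 10 and so on lie mostly above 0 on array 2 only, and the 55 of columns 3, 7, 11 and so on mostly above 0 on array 1 only.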

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

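All tests on the control-named probes were chosen after their values had been seen.

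The 111 probes of set 1 with a control name in their ID were outside the tests, and the ratios of most of them changed sign between the 2 arrays. The 55 in the column class of columns 3, 7, 11 and so on had a median log2 ratio of 0.52 on array 1 (SD 0.28) and -0.37 on array 2 (SD 0.19). The 55 in the column class of columns 2, 6, 10 and so on went the other way, from -0.26 (SD 0.22) to 0.46 (SD 0.12). A trend by well position is argued against, since other probes in the same columns differed between the arrays by only -0.037, against 0.98 for the control-named ones. One array with reversed dyes and its sign turned back stays open. It would also turn a trend tied to the dyes, and the medians of the 32 well positions correlated with r = 0.64 between the arrays. However, no trend was shown to be tied to the dyes. The part over the 8 row classes kept its direction (r = 0.98), while the part over the 4 column classes turned (r = -0.83). In set 2 these parts gave r = 0.99 and r = -0.88. Each column value rests on 4 class means, and on array 1 of set 2 these lay only between -0.010 and 0.0089. That array thus had almost no trend over columns to turn, so whether the turn was particular to set 1 cannot be told. Control RNA added in unequal amounts to the 2 channels, and differently on each array, stays open too with the difference of 0.98, because the amounts are not in the sources used here, and no biological explanation was tested.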

How the results depend on the processing

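No paired analysis was possible because each array already holds DNBR and control RNA, each set has 2 arrays of 1 group, and the sets share no probe. The 8 probes named above kept their direction and stayed past the threshold in all 90 values from other settings. They had been chosen as the most extreme on the same arrays, so this was nearly given by the choice and does not test whether they would repeat. Counts of calls were less stable. In set 1 the 362 limma calls became 607 with arrays scaled to the same spread, 158 with quantile normalisation, 557 with plates centred, 554 with the robust fit, 87 with the regularised t after Cyber-T, 1040 adjusted over both sets, 115 against a change of at most 1.2-fold, 151 at an adjusted p of 0.01 and 710 at 0.1. In set 2 the 7199 calls moved by over 1.5 times with a threshold of 0.01 (3961) and against a change of at most 1.2-fold (2007). The other settings gave 4861 to 8991 in set 2, with 4890 for the test after Cyber-T. Values as deposited turned the split of set 2 from 3343 higher and 3856 lower to 1364 and 3512 (4876 calls). The 2-fold counts under centring and scaling lay between 70 and 88 in set 1 and between 237 and 412 in set 2, and were 171 without plates 56 to 65. Lower clones of set 2 fell from 279 to 163 with plates centred and to 153 with positions and then plates centred, while higher ones went from 76 to 79 and 84. Other fold limits gave 272 (1.5-fold) and 21 (3-fold) in set 1 and 1271 and 102 in set 2. On 1 array alone, 152 to 262 clones of set 1 and 470 to 548 of set 2 were 2-fold from 1, with no test. In set 1 array 1 alone gave 49 higher and 103 lower, and array 2 alone 158 higher and 104 lower. The correlation of the arrays was 0.43 in set 1 and 0.88 in set 2 after centring within positions, and 0.85 in set 2 after centring within plates. Beyond what each setting itself changes, the cause was not tested. Averaging probes of one gene, filters on dim probes, a trend on signal and all gene list settings were not run, since the values carry no gene name and no signal. Leaving out repeated extreme values and adding probes seen on 1 array were not run, since each array's lowest and highest value occurred once and no value was missing. A single array leaves no test of calls.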

Other observations

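Plates 56 to 65 and plate XL0c2 were singled out, and centring within positions or plates was added, after the values had been seen, and the tests on a plate batch, on the contents of plate XL0c2 and on its own adjacent wells were also chosen after the result was seen.

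Plates 56 to 65 were lower than the other numbered plates of set 2, with a difference of medians of -0.31 on the log2 scale. After centring within positions the difference was -0.31, so it did not come from which well positions hold clones on these plates. The same positions recur on every plate, so this centring could remove no other difference between plates. The 75th percentile was also lower (difference -0.23), so the shift was not confined to the lowest clones. A few strongly lower clones could hardly move a median over 3039 clones, so this value was no real test of them. Plates printed or amplified as another batch and plates holding clones of other genes cannot be told apart, because both would give a shift on both arrays, as was seen (-0.31 on the array where it was smaller), and no record of the plates was used here. No biological explanation was tested.

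On plate XL0c2, the ratios of clones in adjacent wells were correlated: across 54 pairs of an odd column and the next even one, r = 0.87 and rho = 0.58. On the other plates the same pairs gave r = 0.23 (7768 pairs) after centring within positions, and r = 0.072 and rho = 0.068 with plates centred too. The pairs of plate XL0c2 hold no difference between plates, so the plate-centred values are the like ones. They argue against adjacent wells being as alike on every plate as on XL0c2, though a weak likeness stays open. A candidate explanation for the 3 clones over 100-fold higher is that these wells hold the injected receptor sequence, or another RNA present in 1 channel. The sequences of the wells were not used here, so it cannot be told apart from a gene strongly expressed in DNBR caps. Even columns of this plate had a median of -0.50 (62 clones) and odd columns of -0.0036 (70 clones), so the columns differed in level although adjacent wells were correlated.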
